A study of Homo sapiens with 5 samples.

How the data were processed

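Gene expression was measured in Jurkat cells, a line of human T cells derived from a leukaemia, on 5 one-colour oligonucleotide arrays. Each array held the RNA of cells expressing 1 construct: green fluorescent protein (GFP) alone, or GFP joined to NLRC5, either in its wild-type form or in 1 of the altered forms called Walker A, Walker B and Walker AB. NLRC5 is a protein of the NOD-like receptor family, and its altered forms are named for the Walker motifs of the nucleotide-binding domain. Per the labels' protocols, total RNA was extracted with TRIzol, cleaned on a column, copied into single-stranded cDNA, fragmented and labelled with biotin. The labels describe the cells both as transiently transfected and as stably expressing the constructs, and which of these holds is not settled here.

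The values are probe intensities on a linear scale, as deposited by the authors, with 1 value per probe set and array. How the authors summarised, background-corrected and scaled them is not given in the sources used here. The array medians lay between 118 and 123, so the arrays had already been brought to a similar scale, and values at or below 1 numbered 21 to 36 per array. No detection call was used, so whether a dim probe lay above background was not determined, and the size of a difference between dim readings is uncertain. The number of arrays limits the precision of every comparison.

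Of the 33252 probes on each array, 21214 were listed in the platform's gene table. Of those, 19460 carried 1 gene symbol and 1754 carried several, and the other 12038 probes are unnamed here. Symbols were updated through the gene identifier with a table of the GRCh38.p14 assembly, which was used for names and for which genes neighbour each other. It matched 19429 of the probes with 1 symbol and changed 0 symbols. No genome build is named with the values, and no coordinates are given. For a gene with more than 1 probe, of which there were 769, the probe of highest mean was taken, which left 18417 genes. Probes with several symbols stayed out of the gene test and are reported by probe number with the symbols listed for them. The values of 565 probes repeat those of another probe on all 5 arrays, so counts of probes are larger than counts of separate measurements.

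Intensities were converted to log2(value + 1). Fold changes are on that scale, which understates the change of dim genes. No further normalization was applied, because the array medians differed by 0.05 on the log2 scale, within the limit of 0.1 set in advance. Groups followed the series' design text, which treats the wild-type and Walker B forms as active (2 arrays) and GFP, Walker A and Walker AB as inactive (3 arrays) and uses the constructs of each class as replicates. How activity had been decided is not given in the sources used here. Each construct was on 1 array, so a p-value measures the spread between different constructs on single arrays, and nothing says that any construct was cultured or hybridised more than once. At most 0.0812% of probes had identical values on any pair of arrays, so no array was a copy of another.

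Active and inactive arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without an intensity trend, two-sided, 3 residual and 3.33 prior degrees of freedom), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Errors given with log2 differences are standard errors (SE) from this fit, and intervals are 95% confidence intervals. A fit with 3 groups gave Walker A and Walker AB minus GFP, and another gave wild-type minus Walker B. Both had 2 residual degrees of freedom and assume that a lone array varies like the other groups. Of 27 gene lists fixed in advance, the 26 with measured members were tested with camera at an inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, in its directional and mixed forms. Each list's members were also adjusted over the list alone. Each construct was set against the GFP array without a test, and a list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins.

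The genes to be named, the lists, the groups and most alternatives were fixed before the data were examined. Named were NLRC5, and the members of the class I partner, class II and butyrophilin lists that passed over the list alone, with up to 4 others of highest mean. Up to 10 genes per direction past the threshold were also named if both active arrays lay on the same side of every inactive array. Where fewer passed, genes were added up to 6 by smallest unadjusted p among those with that separation and a log2 difference of at least 0.5. In every other list the 2 members of largest difference were eligible, and in the other contrasts 5 genes per direction. Exceptions are stated where they occur.

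The limma and camera steps were tested on 20 simulated data sets of 18417 genes with 200 changed genes. For active against inactive arrays, 61.5% of genes changed by 1 on the log2 scale and 92.4% of those changed by 2 were called, and 3.25% of calls were false. Simulations without change gave 0 calls per data set. Camera, at an unadjusted p under 0.05, called 5% of unshifted lists of 20 genes, with 1 such list per data set. This is too few lists for a false-call rate, and the real lists were called at an adjusted p. The simulated noise was normal and independent between genes, so correlated genes and structure among the arrays were not represented. These rates need not hold for the real arrays. The alternatives were quantile normalization, median centring, dropping genes below the median intensity, averaging a gene's probes, testing every probe with a symbol, an intensity trend with and without a robust prior, a pseudocount of 16, a looser threshold of 0.1 and leaving out each array. Testing every probe of the array was added after seeing the data, as were the leave-outs for the 3-group contrasts and the alternatives run on the probes with several symbols and on 8 genes named after their values were seen. The pseudocount of 16 had been fixed only for the counts of genes and was extended afterwards.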

Results

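Expression in Jurkat T cells was measured on 5 arrays, 1 for each of 5 constructs: GFP and the wild-type, Walker A, Walker B and Walker AB forms of GFP-tagged NLRC5. Median intensity was 119.9 on the GFP array, 119.4 with wild-type NLRC5, 118.2 with Walker A, 121.5 with Walker B and 122.7 with Walker AB. The study set the 2 arrays of forms it considered active against the 3 arrays of forms it considered inactive, to ask which genes follow NLRC5 activity. How activity was decided is not given in the sources used here, and if it was decided from class I expression, the class I differences are not independent of the grouping. The wild-type and Walker B arrays were the most alike of the 10 pairs, with a root mean square log2 difference of 0.17 over the 9209 brighter genes, while the other pairs ranged from 0.22 to 0.31.

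NLRC5 itself (probe 7995926) was brighter on all 4 arrays of NLRC5 constructs than on the GFP array. Its intensity was 135.5 with GFP, 512 with the wild-type form, 539 with Walker B, 1155 with Walker A and 1800 with Walker AB. The signal was therefore higher on the arrays of both inactive mutants than on those of both active forms. Active minus inactive arrays gave a log2 difference of -0.32 ± 1.03 (SE, 2 against 3 arrays, limma adjusted p = 0.971). That difference turned positive when Walker A (0.087) or Walker AB (0.41) was left out.

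PSMB9, APOL3 and HBEGF rose on the active arrays. PSMB9 encodes a subunit of the immunoproteasome, which cuts proteins into peptides for MHC class I. Its intensity (probe 8118571) was 1927 with the wild-type form and 2297 with Walker B, against 673 with GFP, 565 with Walker A and 564 with Walker AB. That is a 3.51-fold difference (95% interval 2.80 to 4.39, log2 difference 1.81 ± 0.13 SE). APOL3, an apolipoprotein L family member (probe 8075695), was 3.55-fold higher (2.86 to 4.42), and HBEGF, a growth factor of the EGF family (probe 8114572), was 2.57-fold higher (2.17 to 3.03). On the inactive arrays APOL3 read 53.2 with GFP, 42.9 with Walker A and 49.9 with Walker AB, near the lower quartile of those arrays (49.7 to 51.0). These readings were not shown to be above background, so the size of its fold is uncertain. Each of the 3 genes had an adjusted p of 0.0405 in limma over 18417 genes, with both active arrays above all 3 inactive arrays. In all, 3 genes were higher and 0 lower at the threshold, and 572 higher and 607 lower had an unadjusted p under 0.05, where 921 in total would be expected by chance. Active arrays lay wholly above the inactive ones for 12% of genes and wholly below for 13.2%, against 10% each way by chance. The calls of PSMB9, APOL3 and HBEGF were each lost when any 1 array was left out. The count then fell to 1 without the wild-type array and to 0 without the Walker B, GFP or Walker AB array, while without Walker A it was 2, GZMA and IL26 (IL26 named after its values were seen). With an intensity trend in the variance model the count was 9.

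The classical MHC class I genes could be followed only through probes with several listed symbols: 0 of the 6 heavy chain genes fixed in advance had a probe with 1 symbol. Tested among all 21214 listed probes, 6 such probes were higher on the active arrays (limma adjusted p = 0.0138 for each). The 3 listed under both HLA-B and HLA-C were 4.05-fold to 4.58-fold higher. Probe 8124911 among them read 5347 with the wild-type form and 7011 with Walker B, against 1297 with GFP, 1452 with Walker A and 1267 with Walker AB. The 3 listed under both HLA-B and HLA-F were 3.44-fold to 3.74-fold higher. Probe 8117760 read 703 and 900 on the active arrays against 215, 211 and 209 with GFP, Walker A and Walker AB. These probes cannot be assigned to 1 of the genes they list. In this test 11 probes were higher and 0 lower, the remaining 5 being APOL3, HBEGF and the 3 probes of PSMB9, which hold identical values. All 6 calls were lost without the wild-type, Walker B, GFP or Walker AB array, and 3 of 6 remained past the threshold without Walker A. Fold differences under those leave-outs stayed between 3.09 and 5.24.

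**Figure D1:**
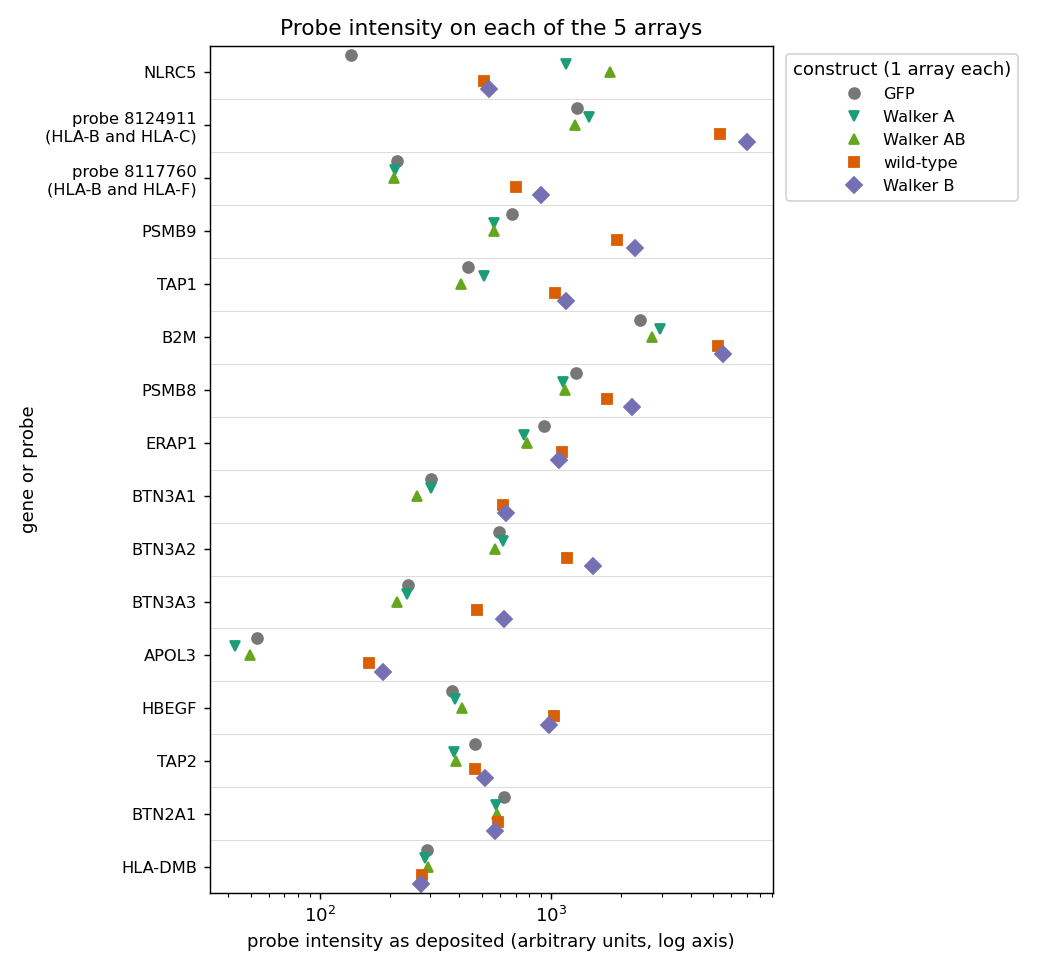
Deposited probe intensity on a log axis for named genes and for 2 probes with several listed symbols, with 1 point per array and construct and no error bar, since each construct has 1 array. PSMB9, TAP1, B2M and the BTN3A genes lie higher with wild-type and Walker B NLRC5 than with GFP, Walker A and Walker AB, while NLRC5 is brightest with Walker AB at 1800.

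Partners of class I and genes of peptide supply were higher on the active arrays in part. Of the 12 genes, all measured, 1 passed over all genes (PSMB9) and 5 passed when adjusted over the list alone: PSMB9, TAP1, B2M, PSMB8 and ERAP1. TAP1, a subunit of the peptide transporter (probe 8125512), was 2.43-fold higher (1.96 to 3.03, adjusted p = 0.161 over all genes and 2.7e-04 over the list). B2M, the light chain of class I molecules (probe 7983360), was 2.0-fold higher (1.65 to 2.44, 0.173 over all genes and 4.1e-04 over the list). PSMB8, another immunoproteasome subunit, gave a log2 difference of 0.74 ± 0.14 (SE) and ERAP1, a peptidase that trims peptides, 0.42 ± 0.12. Among those that did not pass, ERAP2 gave 0.36 ± 0.14, TAP2 0.26 ± 0.13, PSME1 0.17 ± 0.10 and PSME2 0.03 ± 0.13. The list's median log2 difference was 0.31 (camera adjusted p = 1.7e-09), but with an estimated correlation adjusted p = 0.352. With an intensity trend TAP1 and B2M passed over all genes.

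Among butyrophilins, a family of immunoglobulin-like membrane proteins, the 3 BTN3A genes stood apart. BTN3A1 (probe 8117458) was 2.16-fold higher on the active arrays (1.80 to 2.59), BTN3A2 (probe 8117435) 2.24-fold (1.79 to 2.80) and BTN3A3 (probe 8117476) 2.37-fold (1.87 to 3.0). None passed over all genes (adjusted p = 0.161, 0.173 and 0.173), and all 3 passed when adjusted over the list alone, while the other 7 of the 10 measured members did not. Their neighbours BTN2A1 and BTN2A2 gave log2 differences of -0.04 ± 0.10 and -0.15 ± 0.10 (SE). The list's median was 0.02 and its mean 0.34 (camera adjusted p = 0.0221, higher, and adjusted p = 0.369 with an estimated correlation). Its median turned slightly negative when every probe was tested (-0.028) and without the GFP (-0.0030) or Walker B (-0.019) array, and the camera call was lost when every probe was tested and without the GFP, Walker A or Walker AB array. With an intensity trend BTN3A1, BTN3A2 and BTN3A3 passed over all genes.

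MHC class II genes did not pass. Of the 9 measured among 12, 0 passed over all genes and 0 when adjusted over the list alone, with a median log2 difference of 0.04 (camera adjusted p = 0.921). HLA-DMB gave -0.08 ± 0.09 (SE), HLA-DOA -0.13 ± 0.13, HLA-DPA1 0.34 ± 0.15 and HLA-DRB5 0.66 ± 0.37. Another probe of HLA-DPA1 gave 0.65. HLA-DRB5 read 156 with GFP, above 143 with the wild-type form and 149 with Walker B. The members not measured were HLA-DRA, HLA-DRB1 and CD74, so the result does not cover them. HLA-DOA read 77.8 to 103, below the median of every array. HLA-DPA1 read below the median on the inactive arrays, and HLA-DRB5 did so with Walker A (83.9) and Walker AB (59.4). HLA-DMB read above the median on every array (272 to 293). Whether the dim class II readings lay above background was not determined, so the lack of calls does not show that these genes were unchanged.

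**Figure D2:**
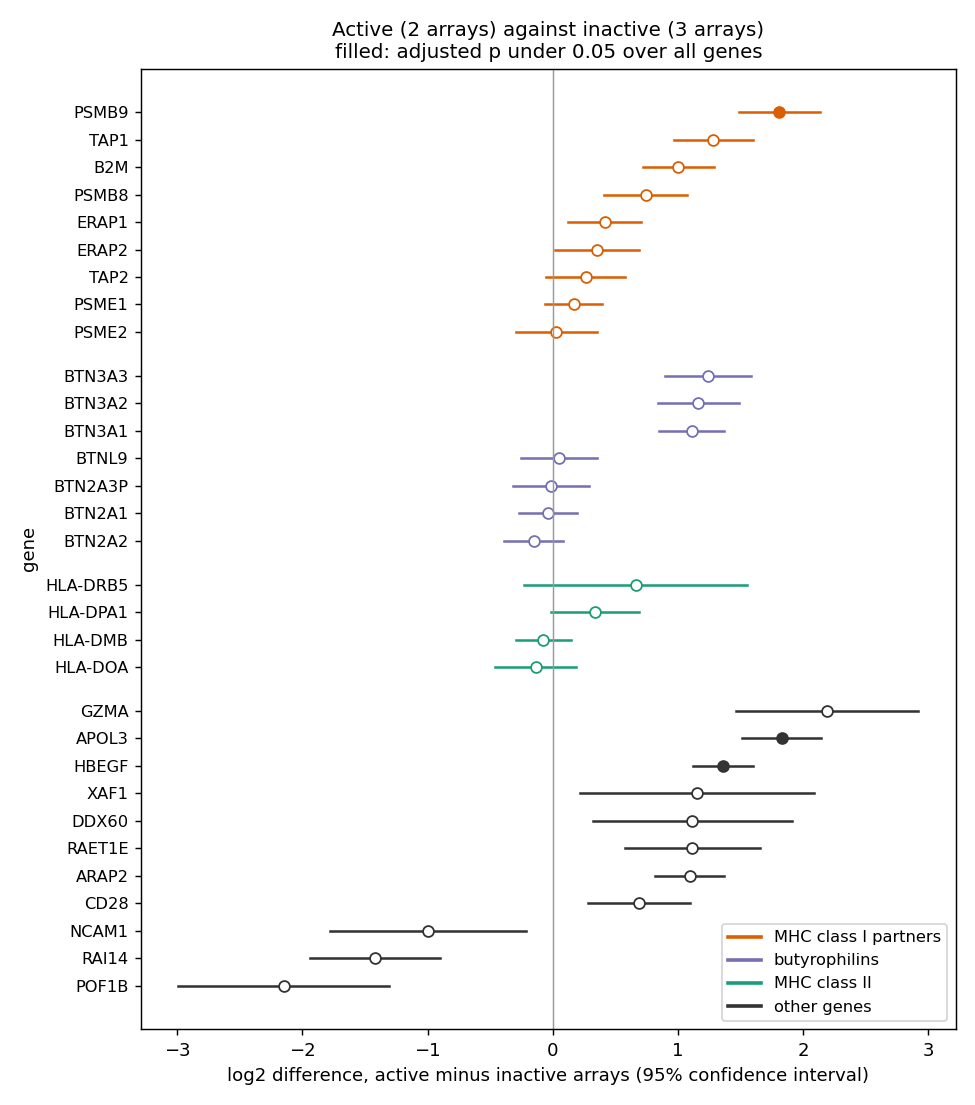
Log2 difference of active (2 arrays) minus inactive (3 arrays) for named genes by group, with bars for the 95% confidence interval and filled points for an adjusted p under 0.05 over all genes. PSMB9 lies at 1.81, APOL3 at 1.83 and HBEGF at 1.36, and the 3 BTN3A genes lie between 1.11 and 1.24. The class II genes shown, a part of those measured, lie between -0.13 and 0.66.

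Against the GFP array alone, the whole list of 12 class I partners had a median log2 difference of 0.18 with the wild-type form and 0.18 with Walker B, at percentiles 99.1 and 99.1 of random lists. With Walker A it was -0.26 and with Walker AB -0.15, at percentiles 0 and 0.57, so part of the list's difference lies in values below GFP on the inactive mutants' arrays. The 5 class I pathway genes and 3 BTN3A genes that passed over their lists had a median fold of 2.01 with wild-type NLRC5 and 2.40 with Walker B. With Walker A the median was 0.993 and with Walker AB 0.895. Of the 8 genes, 6 exceeded 1.5-fold with the wild-type form, 7 with Walker B and 0 with Walker A or Walker AB. These 8 were chosen for their difference, all 4 folds share the GFP array, and they were not tested.

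Interferon-stimulated genes were slightly higher on the active arrays as a list. Of 43 measured, 0 passed over all genes, 1 passed when adjusted over the list alone (MX2, log2 difference 0.72 ± 0.12 SE, named after its values were seen), and 12 had both active arrays above all inactive ones. The median log2 difference was 0.17 (camera adjusted p = 4.7e-07, and adjusted p = 0.352 with an estimated correlation). XAF1 gave 1.15 ± 0.39 and DDX60 1.11 ± 0.33, the largest differences in the list. XAF1 read 180 with the wild-type form and 309 with Walker B, against 170 with GFP, 72.8 with Walker A and 94.2 with Walker AB. No member had both active arrays below all inactive ones, and 31 were separated in neither direction. Among those 31 were MX1 (0.10 ± 0.25), IFI6 (0.11 ± 0.17) and RSAD2 (-0.08 ± 0.13). Against GFP the list's median was 0.12 with the wild-type form and 0.16 with Walker B, at percentiles 99.6 and 99.98 of random lists. It was -0.09 with Walker A and -0.25 with Walker AB, at percentiles 2.0 and 0, so part of this list's difference also lies in values below GFP on the mutants' arrays.

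With the preset correlation alone, camera also placed G2 and M phase genes (median log2 difference 0.10, adjusted p = 0.0042), T lineage genes (0.12), cholesterol synthesis genes (0.14) and replication-dependent histones (0.04, adjusted p = 0.0142 for the last 3) higher on the active arrays. With an estimated correlation these calls were lost (adjusted p = 0.936 for G2 and M phase and for cholesterol synthesis, 0.369 for T lineage and 0.352 for histones). None of their members passed over all genes or over the list alone. Examples are HMMR, of the mitotic spindle, at 0.46 ± 0.13 (SE), CD28, a costimulatory receptor, at 0.69 ± 0.17 (with RAG1, of receptor gene recombination, lower at -0.70 ± 0.20 in the same list), INSIG1, a regulator of sterol synthesis, at 0.69 ± 0.16 and the histone gene H2AC17 at 0.63 ± 0.20. In total 7 of 26 measured lists passed with camera, all higher, 0 with an estimated correlation (smallest adjusted p = 0.352) and 0 with fry's directional test (smallest adjusted p = 0.0612). Fry's mixed test, which asks for change in either direction and compares with no other genes, passed for 4 lists: class I partners (adjusted p = 0.0074), butyrophilins (0.0079), G2 and M phase (0.0280) and epithelial and kidney line markers (0.0074). Without the Walker B array the cholesterol list's median was -0.066 and its call was lost, and the histone call was lost when genes below the median intensity were dropped (adjusted p = 0.115) and without the wild-type or Walker A array. The count of lists was 3 without Walker A and 4 without Walker AB. Against GFP the cholesterol list's median was -0.11 with the wild-type form, 0.27 with Walker B, -0.06 with Walker A and -0.08 with Walker AB. The T lineage list's median was 0.12, 0.045, -0.05 and -0.19 in the same order, so part of its difference lies below GFP on the mutants' arrays.

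The other 19 lists did not pass with camera (smallest adjusted p = 0.390), with medians between -0.06 and 0.06. They were the endoplasmic reticulum chaperones, class I-like molecules, class II genes, enhanceosome genes, NF-kappaB targets, NLR family genes, activation genes, unfolded protein response, heat shock, glycolysis, S phase, ribosomal proteins, apoptosis regulators, and markers of B cells, myeloid cells, cytotoxic cells, erythroid cells, epithelial and kidney lines and fibroblasts. Over their lists alone, RAET1E passed among class I-like molecules (log2 difference 1.11 ± 0.22 SE) and GZMA, a granzyme, among cytotoxic markers (2.19 ± 0.30, adjusted p = 0.404 over all genes, with dim inactive readings of 46.7 to 95.3). The cytotoxic marker NCAM1 gave -0.997 ± 0.324, with a dim reading for Walker B (45.1), and did not pass.

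No gene passed as lower on the active arrays. The 6 of smallest unadjusted p with both active arrays below all inactive ones were RAI14 (log2 difference -1.42 ± 0.21 SE), ZNF737 (-1.10 ± 0.17), POF1B (-2.15 ± 0.35), IFI30 (-0.68 ± 0.11), OR3A2 (-0.85 ± 0.14) and TCP11L2 (-0.56 ± 0.10), with adjusted p between 0.511 and 0.562. POF1B was 60.4 and 30.8 on the wild-type and Walker B arrays, against 156, 280 and 169 with GFP, Walker A and Walker AB. On the higher side, ARAP2 (1.10 ± 0.11) had an adjusted p of 0.161 and did not pass. Readings below the arrays' lower quartile, which leave the size of a difference uncertain, were those of ZNF737 on all arrays, RAI14 on both active arrays, POF1B with Walker B and ARAP2 on the inactive arrays.

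Walker A and Walker AB together were compared with GFP to ask what NLRC5 changed in the forms considered inactive. NLRC5 itself gave the smallest unadjusted p, with a log2 difference of 3.40 ± 0.28 (SE, adjusted p = 0.856). PSMB9 gave -0.25 ± 0.16, TAP1 0.06 ± 0.19, B2M 0.22 ± 0.14 and BTN3A1 -0.10 ± 0.15. No gene passed in limma, while 1044 had an unadjusted p under 0.05 where 921 would be expected. Next by unadjusted p on the higher side were LZTFL1 (1.44), DELEC1 (1.25), TMEM98 (1.26) and GABRR2 (1.12), and on the lower side IFIH1 (-1.16), PGLYRP3 (-0.94), NLRP11 (-1.37), AKR1C3 (-2.06) and OR51F1 (-1.07). All of these but LZTFL1 and TMEM98 read below the lower quartile on the side where they were lower, so the sizes are uncertain. The test had 1 GFP array and 2 residual degrees of freedom, and even NLRC5, which the constructs carry, did not pass. The lack of calls for other genes therefore does not show that these forms left them unchanged. Without Walker A it set 1 Walker AB array against 1 GFP array, and the log2 difference of NLRC5 was 3.72.

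The wild-type and Walker B forms were compared with each other. PSMB9 gave a log2 difference of -0.25 (95% interval -0.78 to 0.28, wild-type minus Walker B), TAP1 -0.17 (-0.72 to 0.39), B2M -0.07 (-0.60 to 0.45) and BTN3A1 -0.04 (-0.54 to 0.45). None of 18417 genes passed in limma, and 299 had an unadjusted p under 0.05 where 921 would be expected by chance. The count lies below that number, so the spread used may be too wide for this contrast. The smallest unadjusted p values belonged to LINC00189 (1.38), AFF1 (1.17), HACD4 (1.87), LMO3 (1.04) and MIR124-1 (1.55) on the higher side and NACA2 (-1.75), HCP5 (-1.31), ISG15 (-1.38), GALNT6 (-0.88) and SNORD13P1 (-1.22) on the lower. LINC00189, HACD4, LMO3, MIR124-1, NACA2 and SNORD13P1 read below the lower quartile on 1 or both of these arrays. HACD4 read 90.7 with the wild-type form and 24.1 with Walker B, both below its 330 with GFP, 398 with Walker A and 261 with Walker AB. Each form was on 1 array, so the intervals rest on the spread of the 3 inactive arrays and do not show that the forms act alike.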

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

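The test of every probe and the tests of explanations (NLRC5 amount, chromosome segment, interferon response, shared handling and cytotoxic cells) were chosen after the values had been seen. The bound set on the splits was written then too, and the bound for the interferon response and the genes of the segment were later revised. A signal appeared in probes that the comparisons between genes leave out, those not listed in the gene table. Among all 33252 probes of the array, 15 unlisted probes were higher on the active arrays past the limma threshold and 1 was lower. The 15 gave log2 differences between 1.71 and 2.24 and had a mean intensity over 100 on the inactive arrays. The 16 together held 14 distinct sets of values, so some repeat one another. They are unnamed here, and no explanation was tested for them.

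The first pattern is the set of genes higher on the active arrays. Of the 10 splits of the 5 arrays into 2 and 3, 1 gave as many called genes, the study's own with 3, and the highest of the others gave 1. So few splits cannot give a share under 0.05. By unadjusted p under 0.05, GFP and Walker AB against the rest gave 1923 genes and the study's split 1179, which points to a structure among the arrays apart from activity. The 2 active arrays were the closest pair (root mean square log2 difference 0.17, next pair 0.22), and shared handling of these arrays cannot be told apart from shared activity because no batch is given and each construct was on 1 array.

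The second pattern is that 8 class I pathway and BTN3A genes had a median log2 difference of 1.13. The amount of NLRC5 RNA argues against more NLRC5 as the cause. The lower of Walker A and Walker AB exceeded the higher active array by 1.10 on the log2 scale (SD of the active arrays 0.05). Among the NLRC5 constructs amount and activity class go together, so an opposite effect of high expression cannot be told apart from activity. NLRC5 protein was not measured here. A gain of the chromosome segment between BTN3A2 and PSMB9 as the whole cause is not borne out, because its 78 bright genes, those of the pattern included, had a median of 0.0039 (upper quartile 0.12), and 2 of the 8 genes lie on other chromosomes. A general interferon response stays open, because the 8 genes were chosen for their difference and, list against list, 43 interferon-stimulated genes had a median of 0.17 (upper quartile 0.51, 12 with both active arrays higher) and the 12 class I partners 0.31. NLRC5 activity may account for the pattern, as the series' title proposes for class I genes. However, an interferon response, shared handling of the active arrays and an opposite effect of high NLRC5 expression stay open for these genes too.

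The third pattern is GZMA, whose log2 difference of 2.19 did not pass over all genes. Cytotoxic cells among the cultured cells would bring their other transcripts, and the 11 other markers had a median of 0.0082 (upper quartile 0.15). GZMA was picked as the largest difference of its list, so other markers lying below it cannot count against such cells. Some also varied widely between arrays, such as GZMB (0.06 ± 0.70 SE) and PRF1 (-0.01 ± 0.38). The explanation is therefore not decided by these values. GNLY, abundant in such cells, gave 0.03, while NKG7 gave 0.77 and GZMK, a granzyme outside the list, 1.85, both in the direction of GZMA. Without Walker A GZMA passed over all genes (adjusted p = 0.0434, range over the alternatives 0.0434 to 0.9999), and differences between separately made cultures were not tested.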

How the results depend on the processing

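The tests of every probe of the array and the leave-outs for the 3-group contrasts were chosen, and HCP5, GZMK, GZMB, GNLY, NKG7, MICA, MICB and MX2 were named, after seeing the data. The count of genes higher on the active arrays (3) was 11 when every probe with a symbol was tested, 26 for every probe of the array (with 1 lower), 9 with an intensity trend and 8 with a robust prior added, and 0 to 2 when 1 array was left out. More entries are tested at probe level, several of them repeats. With the trend B2M, TAP1, BTN3A1, BTN3A2, BTN3A3 and HCP5 joined APOL3, HBEGF and PSMB9. Genes lower stayed at 0 in every leave-out. Lists past camera (7) ranged from 3 to 6 when 1 array was left out. The NLRC5 difference (-0.32) ranged from -1.45 to 0.41, reversed at 0.087 and 0.41, because Walker A and Walker AB carry its highest signal. Inactive mutants against GFP ranged from 0 to 1 gene.

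For the values that reversed the cause was not tested. PSME2 was -0.0033 with quantile normalization and ranged from -0.062 to 0.11 when 1 array was left out. The butyrophilin median was -0.028 in both probe-level tests and ranged from -0.019 to 0.065 in the leave-outs. In the leave-outs BTN2A3P ranged from -0.12 to 0.091, BTNL9 from -0.035 to 0.12, HLA-DOA from -0.31 to 0.042, CD68 from -0.54 to 0.24, GZMB from -0.73 to 0.85, GNLY from -0.0048 to 0.10 and the cholesterol median from -0.066 to 0.38. Among values for single genes, probes and lists, 1669 kept direction and side of the threshold, 16 became stronger, 53 weaker and 19 reversed. The intensity trend, the robust prior and the looser threshold leave a gene's difference unchanged. Most of these values were not past the threshold at the start, so keeping their side says little. The adjusted p of PSMB9 ranged from 0.0020 to 0.579 over the alternatives. The 8 class I pathway and BTN3A genes kept a positive difference in all 14 alternatives that give one. They were chosen for their difference, and each had both active arrays above every inactive array. Leaving out 1 array therefore could not reverse their sign. Signal over background could not be used, since no detection call was used here.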

Other observations

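HCP5 and GZMK were singled out after their values were seen, and so was the choice of MICA, MICB and GZMB from the lists fixed in advance. HCP5, a long noncoding RNA gene of the MHC class I region (probe 8118111), read 177 with wild-type NLRC5 and 438 with Walker B, against 29.9 with GFP, 24.6 with Walker A and 28.5 with Walker AB. The log2 difference was 3.29 ± 0.35 (SE, limma adjusted p = 0.169) and did not pass over all genes. It passed with an intensity trend, but not with a robust prior added, and without the wild-type array (adjusted p = 0.0214, range over the alternatives 0.0214 to 0.608). The inactive readings lie below the lower quartile of those arrays (49.7 to 51.0) and were not shown to be above background, so the size is uncertain, and the fold moved from 9.78 to 15.4 without the wild-type array and to 6.22 without Walker B. The class I-like genes MICA and MICB of the same region gave log2 differences of 0.22 ± 0.17 and 0.19 ± 0.15 (SE).

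GZMK and GZMA are granzyme genes on the same chromosome. GZMK (probe 8105331) read 183 and 139 on the wild-type and Walker B arrays, against 41.4 with GFP, 78.2 with Walker A and 25.3 with Walker AB, a log2 difference of 1.85 ± 0.43 (SE, limma adjusted p = 0.660). GZMA read 262 and 307 against 51.5, 95.3 and 46.7. Both were thus brighter with Walker A than with GFP or Walker AB, and GZMB, another granzyme, was brightest with Walker A at 2748, with 2088 for the wild-type form, 697 for Walker B, 869 for GFP and 646 for Walker AB.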
